A study of Salmonella enterica subsp. enterica serovar Typhimurium with 5 samples.

How the data were processed

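RNA polymerase and RpoD binding was measured by ChIP-chip in Salmonella enterica serovar Typhimurium strain SL1344. The 5 two-colour Agilent tiling arrays fall into 3 groups by their labels. RNAP, precipitated with an antibody against the polymerase β′ subunit, has 2 arrays. RpoD has 2 arrays, and RNAP after rifampicin has 1. The labels describe the arrays of a group as biological replicates. Per the labels, ChIP DNA carried Cy3 and input DNA carried Cy5 on every array, so that no dye swap separates the dye from the precipitation.

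Per the file headers, spot intensity was read with Agilent Feature Extraction 10.5.1.1, and the deposited processed intensity of each channel was background-subtracted and linearly dye-normalised. The deposited scanner files also hold log10 ratios, whose sign was found to be input over ChIP. These log10 ratios were not used here. The series value table holds log2 ratios that the authors deposited with no stated scale. Compared spot by spot with the scanner files, each column equalled the log2 of background-subtracted Cy3 over background-subtracted Cy5 minus a constant, on chromosomal probes. The medians of these deposited log2 columns were 5e-06 and 0.00528 for RNAP replicates 1 and 2, 5.2e-05 and 8.9e-05 for RpoD replicates 1 and 2, and 1e-06 for the rifampicin array, so each had been centred on its median.

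The array holds 42021 chromosomal probes of 60 nt with a median spacing of 111 bp and a largest gap of 358 bp. It holds a further 564 probes for pSLT, 786 for Col and 81 for pRSF, the plasmid sets as the probe names give them, each probe placed only within a window of 1000 bp. For each probe the log2 ratio of processed Cy3 over processed Cy5 was computed and centred on the median of the chromosomal probes of its array, with no loess step. Spots that the scanner software marked as outliers were left out. These made up 20.1% and 2.26% of spots on RNAP replicates 1 and 2, 4.91% and 0.71% on RpoD replicates 1 and 2, and 28.9% on the rifampicin array.

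The design set before the data were examined assumed gene bodies and promoter windows. The chromosomal probe names carry the identifier of a reference sequence, but no genome build is named for the positions, which run to 4877972. Whether these positions lie on that sequence was not checked. The gene table at hand belongs to another strain and gave no safe match. No position was therefore converted and no gene name is printed, and the tests on gene lists, promoters and gene bodies were not run. Their place was taken by windows of 500 bp with at least 2 probes in every array (8651 windows) and by sites. A bound region was a run of at least 3 consecutive probes with a log2 ratio of at least 1 in every array of its group. A site is the summit of such a region, found from means over 150 bp on either side. The summit level is the mean within 250 bp of the summit, and the flank level is the mean at 750 to 1500 bp on either side. Positions count from 1 on the array's design sequence. A level that averages in a spot saturated in the ChIP channel is a lower bound.

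Group means and differences were tested with limma 3.58.1 in R 4.3.3 on all 5 arrays, two-sided, with the group as the only term. The fit has 2 residual degrees of freedom and a moderated prior of 6.67. The spread of the lone rifampicin array was assumed to be that of the other groups. A single array cannot test this, and across probes its log2 ratios had the widest spread, with a scaled median absolute deviation of 1.26 against 0.85 to 1.07. If its error was larger too, the p-values against it are too small. Adjusted p-values are Benjamini-Hochberg values over all windows or sites of a comparison, with a threshold of 0.05. Overlaps of regions were set against 1000 circular shifts of the regions along the chromosome. Intervals of profile values are 95% bootstrap intervals from 1000 draws of sites or regions, so that they cover the spread among sites within these arrays and not between cultures. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

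The limma step was tested on simulated data of 8651 windows, of which 100 were changed by a log2 of 1 and 100 by a log2 of 2. For RpoD against RNAP, 5% of the smaller and 75% of the larger changes were recovered, with 2 false calls. For rifampicin against RNAP, none of the smaller (0%) and 20% of the larger changes were recovered, with 1 false call. Every simulated array had the same error spread, so the false calls do not show what a wider error on the rifampicin array would give. The region step found 48 of 48 simulated sites, with a median summit error of 31.0 bp. These were high, evenly spaced peaks with no spots left out.

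The windows named in the text follow a rule set in advance for genes and applied to windows. It takes the 10 highest and the 10 lowest values in each comparison among those past the threshold with the same sign in every array or pair of arrays, with neighbours within 2000 bp merged. Of the 10 lists the text prints the first 2 or 3 windows of 6. It prints none from the lists below the median for RNAP and for RpoD, nor from either list of RpoD against rifampicin. Since the same sign was required, it is no support for a named window. Regions named for another reason are marked as chosen after their values were seen.

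RNAP replicate 1 and RpoD replicate 1 shared a slide and a scan session, as did RNAP replicate 2 and RpoD replicate 2. The rifampicin array was alone on its slide and in its session. Alternatives changed the background correction (normexp with an offset of 50, on median spot signals because the files hold no mean signals), loess, scaling, quantile normalisation, centring, the source of the values, filters on dim and saturated probes, the number and summary of probes, the prior, the arrays used, and blocks for the replicate number and the slide. Window sizes of 1000 and 250 bp, outlier spots kept, other definitions of sites and flanks, and the removal of each array's running median over 200 kb were added after seeing the data.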

Results

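The series maps where core RNA polymerase and its housekeeping sigma factor sit on the chromosome of Salmonella Typhimurium SL1344, and where polymerase sits after rifampicin. RNAP denotes the signal from an antibody against the β′ subunit of core polymerase. RpoD is the sigma factor that brings core polymerase to most promoters of growing cells. Rifampicin binds the β subunit and blocks the extension of short transcripts, so that polymerase cannot leave a promoter while polymerase already within a gene can finish. Cells grew in Luria broth at 37 °C to an OD600 of 2.0, and the treated culture received 150 µg/ml rifampicin for 20 min. There were 2 RNAP arrays, 2 RpoD arrays and 1 rifampicin array, each with input DNA in the other channel. The median ChIP intensity before correction ran from 4513 on the rifampicin array to 13504 on RNAP replicate 2. On RNAP replicate 2, 62.8% of spots were well above background in the ChIP channel, against 96.4% to 99.7% on the others. Between 0.17% and 1.30% of spots were saturated in the ChIP channel, and the number of arrays limits the precision of every value.

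In untreated cells RNAP covered short peaks and some long stretches of the chromosome. It formed 620 bound regions with a median length of 555 bp, which covered 9.21% of the design sequence. The number depended on the definition and was 366 at a height of 1.5, 377 with runs of 5 probes, 392 after loess and 191 with the height at the 95th percentile of each array. Of these, 18 were 2000 bp or longer, and the longest ran for 7669 bp, from 2384580 to 2392248 on the array's design sequence. The RNAP level over that region was at least 2.50 ± 0.28 (log2 over input, SD, n = 2), with 17 of 58 values saturated on replicate 1 and 28 of 65 on replicate 2, while the RpoD level was 0.49 ± 0.05 (SD, n = 2). The highest window lay at 2855001 to 2855500, with a log2 of 3.63 ± 0.19 (SD, n = 2) and a limma adjusted p of 7.1e-05, and its centre was 22 bp from an RpoD summit. In the window from 974501 to 975000 RNAP reached at least 3.56 ± 0.48 (SD, n = 2) and RpoD at least 4.31 ± 0.37 (SD, n = 2), with 1 of its 5 probes saturated on all 4 of these arrays.

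By limma, two-sided, 2313 of 8651 windows were above the chromosome median for RNAP and 2142 were below it, at the adjusted threshold of 0.05. The count below fell to 163 when dim probes were left out, which left 5319 windows, and to 1181 after loess, against 1742 above it after loess. Without RNAP replicate 1 the counts were 1423 and 892.

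RpoD formed more regions than RNAP and fewer long ones. There were 816 RpoD regions with a median length of 592.5 bp, of which 9 were 2000 bp or longer, with the longest at 2650 bp. On single arrays, 18 and 12 RpoD regions were 2000 bp or longer on replicates 1 and 2, against 60 and 21 RNAP regions. RpoD replicate 1 alone had a region of 4853 bp, and the contrast in long regions was weak against RNAP replicate 2. Runs of 5 probes gave 539 RpoD regions and the 95th percentile 260. The highest RpoD windows lay at 1068501 to 1069000 and at 2623501 to 2624000. All 3 probes of the first were saturated on both RpoD arrays, so its level was at least 4.84 ± 0.50 (log2, SD, n = 2, limma adjusted p = 6.7e-06). The second read at least 4.66 ± 0.03 (SD, n = 2, limma adjusted p = 6.7e-06), with 4 of its 5 probes saturated on both. RNAP levels in these windows were at least 3.23 ± 0.28 and 3.12 ± 0.55 (SD, n = 2), each with saturated probes on 1 RNAP array.

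By limma, two-sided, 2041 windows were above the chromosome median for RpoD and 1285 below it. The count below was 577 when arrays were centred on the mode (2305 above), which moved the median of all windows from -0.01 to 0.16; it was 549 after loess (1671 above) and 195 without dim probes. Leaving out RpoD replicate 1 or 2 gave 426 or 648 windows below.

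Most RNAP regions overlapped a called RpoD region, and a smaller share of RpoD regions overlapped a called RNAP region. A region with no overlap need not lack polymerase, because a called region had to reach a log2 of 1 on both arrays. Of 713 RpoD sites, only 63 (8.84%) had an RNAP level under 0.5 on both untreated arrays. Of the RNAP regions, 76.3% overlapped an RpoD region, against a mean of 22.0% after circular shifts. Of the RpoD regions, 57.2% overlapped an RNAP region, against a mean of 16.6% and a maximum of 20.3% after 1000 shifts. RpoD replicate 1 regions overlapped those of replicate 2 in 79.9% of cases, and RNAP replicate 1 regions those of replicate 2 in 68.4%.

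The labels' antibody comparison, RpoD against RNAP in untreated cells, asks where the signals of the sigma factor and of core polymerase part. RpoD and RNAP were precipitated with different antibodies, and each ratio is relative to its array's median. A difference between them therefore compares signals and not the amounts of protein bound. The largest excess of RNAP over RpoD lay inside long RNAP regions. In the window from 2391001 to 2391500, inside the longest RNAP region and with its centre 3460 bp from the nearest RpoD summit, RpoD minus RNAP was -3.34 (log2, limma adjusted p = 0.00345), with RNAP at 2.80 ± 0.21 and RpoD at -0.54 ± 0.14 (SD, n = 2 each). At 3710501 to 3711000, inside the region from 3709298 to 3712170, the difference was -3.22 (limma adjusted p = 0.00345), and at 3088501 to 3089000, outside the 10 longest RNAP regions, it was -2.99 (limma adjusted p = 0.00394). Probes were saturated on both RNAP arrays in the first and second of these windows and on RNAP replicate 1 in the last, and on no RpoD array, so that the RNAP levels and the sizes of the 3 differences are lower bounds. RpoD exceeded RNAP in windows beside RpoD summits and, with a wider spread of replicates, in some windows far from them. At 4372001 to 4372500 the difference was 2.23 (limma adjusted p = 0.0087), with RNAP at 1.00 ± 0.06 and RpoD at 3.23 ± 0.31 (SD, n = 2 each), and the window's centre lay 347 bp from an RpoD summit. Larger differences, of 2.74 at 230001 to 230500 (limma adjusted p = 0.027) and 2.49 at 4396001 to 4396500 (limma adjusted p = 0.0219), lay 6678 bp and 9200 bp from any RpoD summit. RNAP replicates had an SD of 1.35 and 0.89 there, and neither call was kept without RNAP replicate 1, where the differences were 1.79 and 1.86. After loess 5 of these 6 windows lost the call. Among them were 2391001 (-2.20, limma adjusted p = 0.0555), 3088501 (-1.84, limma adjusted p = 0.0647) and 4372001 (limma adjusted p = 0.0647). The window at 230001 also lost it after normexp and with the robust prior. Its difference ran from 2.06 to 2.97 under the alternatives that kept all RNAP and RpoD arrays.

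By limma, two-sided, RpoD exceeded RNAP in 429 windows and was lower in 399, with a median difference of 0.16 over all windows. With the slide as a block the counts were 891 and 653. Of the higher windows, 55.5% overlapped a region bound after rifampicin, against 22.8% to 31.9% in shifted windows (central 95% of shifts), and of the lower windows 28.1% did, against 21.3% to 33.1%.

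After loess within arrays no window was higher and 1 was lower by limma (0 and 1), with 764 higher and 633 lower at an unadjusted p under 0.05; the counts were 788 and 519 with arrays scaled to a common spread, 312 and 537 after quantile normalisation, 277 and 388 after normexp, and 467 and 302 when centred on the mode. They were 64 and 83 without RNAP replicate 1, 185 and 244 without RpoD replicate 1, and 670 and 384 without RpoD replicate 2.

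RNAP signal reached further from RpoD summits than RpoD signal did. Around the 816 RpoD summits, mean RpoD fell from 2.20 on both arrays within 250 bp to 0.23 and 0.24 at 750 to 1000 bp. Mean RNAP fell from 1.41 and 1.27 to 0.47 and 0.28. Measured above the level at 2000 to 3000 bp, RNAP at 750 to 1000 bp kept 17.9% (interval 13.0% to 22.9%) and 11.1% (6.77% to 15.4%) of its summit level on replicates 1 and 2. RpoD kept 0.31% (-2.74% to 3.36%) and -0.04% (-3.04% to 2.94%). The difference, RpoD minus RNAP within a slide, was -17.6 percentage points (-21.5 to -13.7) for replicate 1 and -11.1 (-14.1 to -7.94) for replicate 2. These summits were chosen on the RpoD arrays themselves, which favours a sharp RpoD peak. At summits chosen on the rifampicin array instead, RNAP kept 13.8% and 9.24% and RpoD -4.29% and -1.62% on replicates 1 and 2. The differences there were -18.1 percentage points (-23.1 to -13.8) and -10.9 (-14.9 to -7.35).

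**Figure D1:**
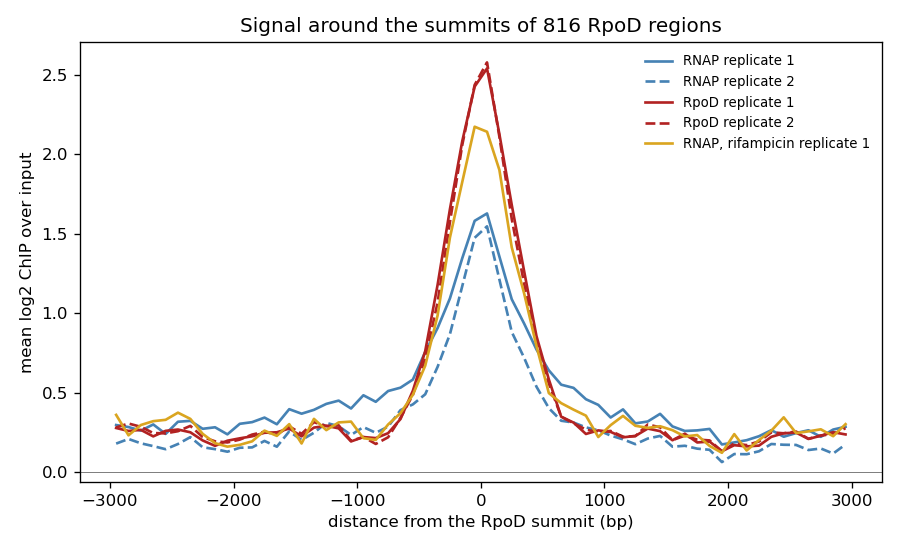
Mean log2 ChIP over input (vertical axis) by distance from the RpoD summit in bp (horizontal axis), over 816 RpoD regions, with a line per array. Within 250 bp RpoD averages 2.20 on both arrays, rifampicin-treated RNAP 1.90 and untreated RNAP 1.41 and 1.27, and untreated RNAP replicate 1 stays highest at 750 to 1000 bp, at 0.47.

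A like contrast showed in the correlation between probes along the whole chromosome. The correlation of log2 ratios between probes about 1000 bp apart was 0.42 and 0.29 on the RNAP arrays, 0.12 and 0.11 on the RpoD arrays, and 0.21 on the rifampicin array. As a ratio to the correlation at about 100 bp, this was 0.479 and 0.406 for RNAP, 0.136 and 0.140 for RpoD and 0.232 after rifampicin. These are correlations across probes, which are not independent replicates.

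**Figure D2:**
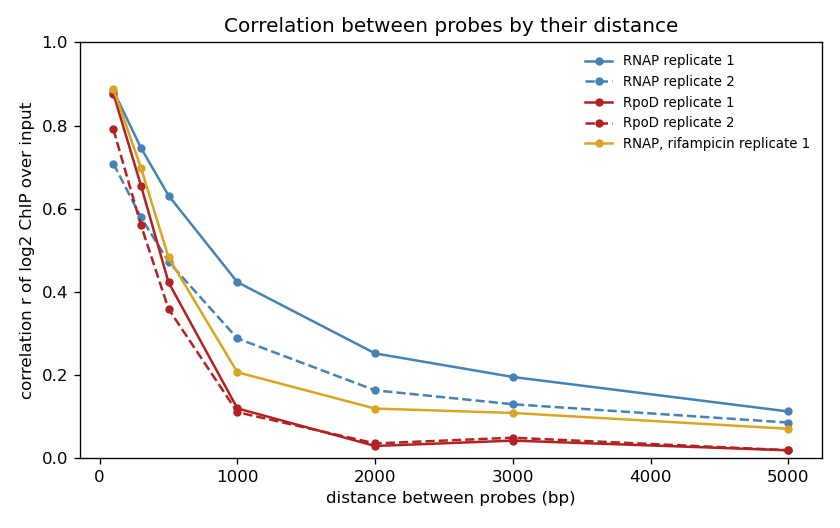
Correlation r of log2 ChIP over input between chromosomal probes (vertical axis) by the distance between them in bp (horizontal axis), with a line per array. At 1000 bp the RNAP arrays lie at 0.42 and 0.29, the rifampicin array at 0.21 and the RpoD arrays at 0.12 and 0.11.

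The comparison of RNAP with and without rifampicin asks where polymerase held at initiation is found. After rifampicin, polymerase was higher on average at RpoD sites and lower along most of the long RNAP regions. At 713 RpoD sites with enough probes the mean summit level was 1.90 with rifampicin, against 1.42 and 1.28 on the untreated RNAP arrays. Along the longest RNAP region, from 2384580 to 2392248, the RNAP level was at least 2.50 ± 0.28 untreated (SD, n = 2) and 0.45 with rifampicin, with an RpoD summit at 2387790. The region from 4315501 to 4319432 differed by -1.76, that from 1971763 to 1974812 by -1.58 and that from 3709298 to 3712170 by -1.30 (log2, rifampicin minus RNAP). These 3 were chosen among the 10 longest RNAP regions after their values were seen, and in 1 of the 10, from 1710087 to 1713649, the difference was positive, at 0.17. In these 4 regions probes were saturated on both untreated arrays and none after rifampicin, so that the falls may be larger and the 0.17 smaller.

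**Figure D3:**
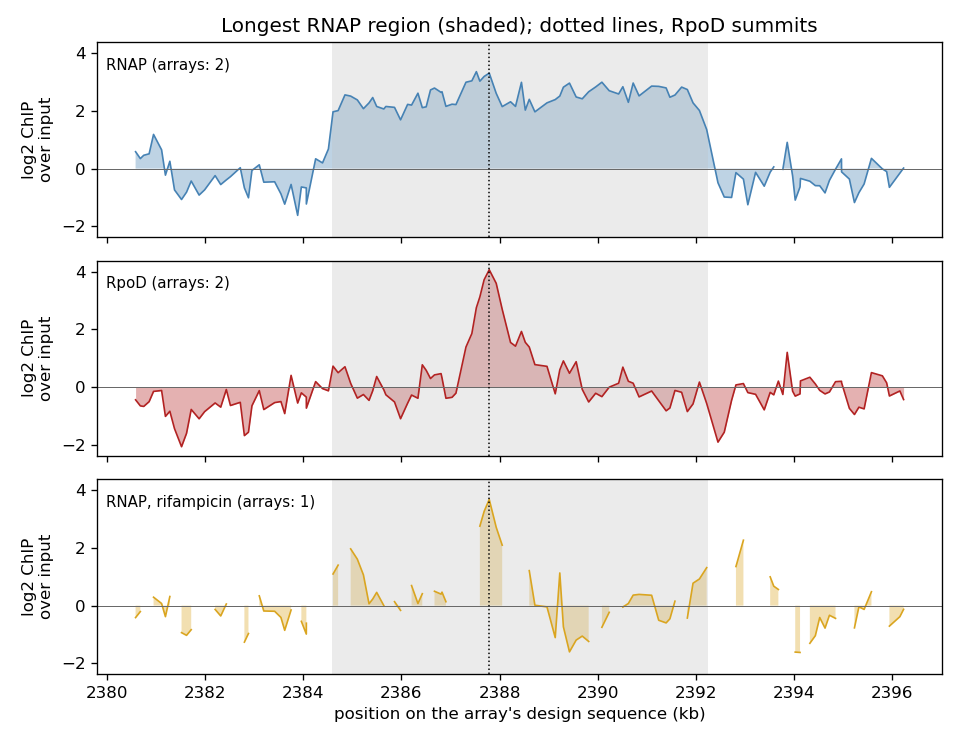
Mean log2 ChIP over input (vertical axes) per probe by position on the array's design sequence in kb (horizontal axis) for RNAP, RpoD and rifampicin-treated RNAP, with gaps where spots were left out, the longest RNAP region shaded and its RpoD summit dotted. RNAP averages 2.50 over the shaded region, RpoD 0.49 and rifampicin-treated RNAP 0.45, and the last peaks at the RpoD summit.

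At the RpoD sites, limma called the summit level higher after rifampicin at 263 of 713 and lower at 34, two-sided at an adjusted 0.05, with the spread of the single rifampicin array taken from the other groups. The difference was positive at 76.3% of sites, with a mean of 0.55. The summit minus flank value rose at 283 sites and fell at 52, with a mean difference of 0.61. The flank level itself rose at 89 sites and fell at 108, with a mean difference of -0.06, and this direction was not stable. It was 99 up and 50 down when centred on the mode (mean 0.11), 109 and 89 in the series value table (mean 0.03), 70 and 44 after loess (mean 0.04), 51 and 47 without the chromosome trend (mean -0.04), and 94 and 62 without RNAP replicate 1 (mean 0.02). With arrays scaled to a common spread, summit levels were higher at 79 sites and lower at 20, and summit minus flank values at 79 and 21; after quantile normalisation the summit counts were 101 and 56. After loess the summit minus flank counts were 166 and 10, and after normexp 66 summit levels and 85 summit minus flank values fell. The mean summit difference was 0.16 with the common spread, 0.11 after quantile normalisation and 0.29 after normexp, and the mean summit minus flank difference was 0.26, 0.27 and 0.35. When RpoD sites were called without RpoD replicate 2, the summit level was lower at 88 sites, with a mean difference of 0.33.

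The flank of RpoD sites held a smaller share of the polymerase signal after rifampicin. Above the level at 2000 to 3000 bp, rifampicin-treated RNAP at 750 to 1000 bp kept 0.97% (-4.40% to 5.89%) of its summit level. The difference from untreated RNAP was -16.9 percentage points (-21.7 to -12.3) for replicate 1 and -10.1 (-14.6 to -5.58) for replicate 2, and under the alternatives it ran from -22.5 to -9.65 and from -15.2 to -7.39. In long RNAP regions chosen on replicate 1, probes more than 500 bp from any RpoD summit differed from untreated replicate 2 by a median of -0.67 (-1.06 to -0.37), lower in 43 of 60 regions. In those chosen on replicate 2, they differed from replicate 1 by -0.93 (-2.04 to -0.51), lower in 16 of 21 regions. Within 500 bp of an RpoD summit the same regions differed by 0.42 (0.20 to 0.63) and by 0.02 (-0.33 to 0.30). Under the alternatives the medians away from RpoD summits ran from -1.32 to -0.37 and from -1.94 to -0.43. Leaving out saturated probes brought the -0.93 to -0.71, with an interval of -1.15 to 0.13 that includes 0.

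Over all windows, the largest fall after rifampicin lay inside the longest RNAP region and the largest gains in windows with little RpoD. The window from 2389501 to 2390000, inside the longest RNAP region, differed by -3.88 (log2, limma adjusted p = 0.0045), from 2.72 ± 0.30 (SD, n = 2) to -1.16. On RNAP replicate 2, 3 of its 4 values were saturated, so that the untreated level and the size of the fall are lower bounds. The window from 3240001 to 3240500 differed by -3.61 (limma adjusted p = 0.0052), from 1.31 ± 0.57 (SD, n = 2) to -2.30. The rifampicin value there rests on 2 of its 3 probes and lies far below the array median. At 2989001 to 2989500 the difference was 3.45 (limma adjusted p = 0.0045), from 0.33 ± 0.22 (SD, n = 2) to 3.78, with RpoD at -0.79 ± 0.17 (SD, n = 2). At 1292001 to 1292500 it was 3.40 (limma adjusted p = 0.0045), with RpoD at -0.61 ± 0.41 (SD, n = 2).

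Limma, two-sided, called 998 windows higher after rifampicin and 655 lower. Of the higher windows 27.5% overlapped an RpoD region, against 16.5% to 21.9% after shifts, and of the lower windows 8.55% did, against 15.6% to 22.6%. The calls also differed along the chromosome, with 313 higher and 66 lower windows between 1000 and 2000 kb and 118 higher and 206 lower between 3000 and 4000 kb. With each array's running median over 200 kb removed, 944 were higher and 570 lower, of which 805 and 476 were the same windows. The input channel of the rifampicin array also varied along the chromosome by 0.137 more than the untreated inputs (amplitude of a single wave, log2).

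The counts were 366 and 295 with arrays scaled to a common spread, 409 and 398 after quantile normalisation, 884 and 326 after loess and 1146 and 448 when centred on the mode, which moved the median difference of all windows from 0.07 to 0.22. With the replicate number as a block they were 1244 and 1174, although that block groups the rifampicin array with replicates 1 of another slide. Without dim probes 507 were higher, and without RNAP replicate 1 there were 427 lower; the single rifampicin array was alone on its slide, so that the treatment and the slide cannot be told apart.

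**Figure D4:**
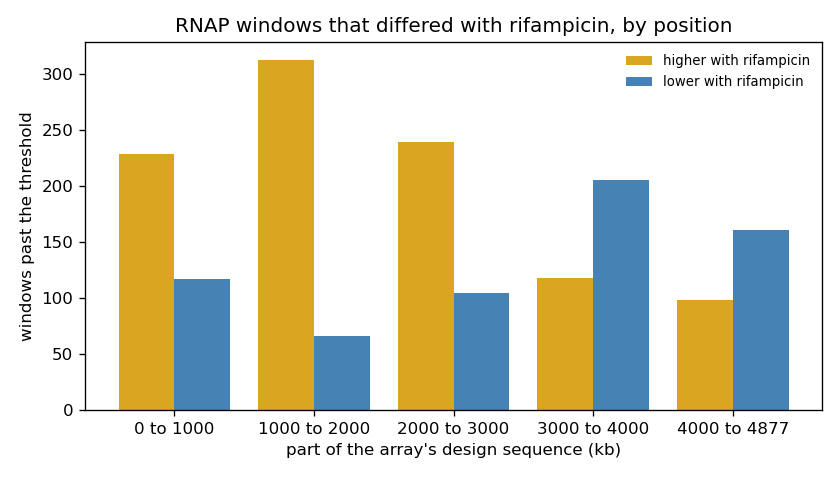
Number of windows called higher or lower by limma in rifampicin-treated against untreated RNAP (vertical axis) in parts of the design sequence in kb (horizontal axis). Between 1000 and 2000 kb 313 windows are higher and 66 lower, and between 3000 and 4000 kb 118 are higher and 206 lower.

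Polymerase after rifampicin and RpoD shared many sites. Rifampicin-treated RNAP formed 1052 regions with a median length of 653 bp (626 with runs of 5 probes and 239 at the 95th percentile). These had to pass on 1 array only, where the other groups needed 2. Called on single arrays, there were 747 and 683 RNAP regions and 971 and 916 RpoD regions on replicates 1 and 2. Of the rifampicin regions 39 were 2000 bp or longer, the longest at 4046 bp, against 60 and 21 on the single RNAP arrays. Of the RpoD regions, 73.4% overlapped a rifampicin region, against a mean of 29.8% after shifts. In the other direction 54.7% of the rifampicin regions overlapped an RpoD region, against a mean of 22.9%. With the height set at the 95th percentile of each array these shares were 40.4% and 44.4%. Of 979 rifampicin sites with enough probes, 226 (23.1%) had an RpoD level under 0.5 on both RpoD arrays. The highest of these 226, at 1958773, had a rifampicin level of at least 4.44, with 1 of its 5 probes saturated on that array, and with RNAP at 1.67 and 1.01 and RpoD at -0.09 and 0.21 on replicates 1 and 2. Of 713 RpoD sites, 67 (9.40%) had a rifampicin level under 0.5.

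At the 979 rifampicin sites, limma called the RpoD minus RNAP difference of summit minus flank higher at 307 and lower at 85, two-sided, with a mean of 0.36 (345 and 107 with the slide as a block). After loess these counts were 123 and 27, and 197 sites were higher without saturated probes. Without RNAP replicate 1 there were 55 lower sites, and without RpoD replicate 1 there were 34. Over windows, RpoD was above rifampicin-treated RNAP in 792 and below it in 793. These counts were 295 and 678 after loess, 573 and 373 with arrays scaled to a common spread, and 366 and 475 without RpoD replicate 1. Quantile normalisation gave 269 and 384, the replicate block 1297 and 985, and the removal of dim probes 666 and 453.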

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

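The test against a wider spread was chosen after the input signal had been seen, and the other tests of this part were set before their results were seen. The input channel of the rifampicin array, which no comparison uses on its own, varied along the chromosome by a wave of amplitude 0.208 (log2, 95% interval 0.176 to 0.241), against 0.068 to 0.0904 on the untreated inputs, and the difference of 0.137 (0.115 to 0.157) was highest near 4241 kb and lowest near 1802 kb. A wider overall spread of that array as the whole source is argued against by the slope of its input on the untreated inputs, which was 0.747 higher across stretches of 100 kb than within them (0.455 to 1.08). Uneven labelling of the Cy5 input alone may be a source and stays open, because the Cy3 channel of the array differed from untreated RNAP by an amplitude of 0.186 (0.123 to 0.261) but peaked 2045 kb away from the Cy5 peak. The wave of the rifampicin input itself peaked near 4085 kb, against 3765 to 3905 kb on the untreated inputs. A change of DNA copies along the chromosome with rifampicin also stays open, measured by the same 0.137. No untreated array shared the slide and a single treated culture was measured, so that treatment, culture and slide cannot be told apart. With polymerase unmoved, more copies would raise Cy3 in the same places, whereas the Cy3 difference peaked near 1407 kb and was lowest near 3846 kb. This excludes nothing here, because the Cy3 channel also carries any shift of polymerase with rifampicin.

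On the Col plasmid, whose 87 windows enter no comparison of the report, rifampicin minus RNAP had a median of 0.90 (log2), and this difference was not tested across arrays. On pRSF, with 9 windows, RpoD replicate 1 had a median of 0.80 (log2), above RpoD replicate 2 at -0.94 and the RNAP replicates at -0.86 and -1.75, and no explanation was tested.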

How the results depend on the processing

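Window sizes, outlier spots kept, the site and flank alternatives and the removal of the chromosome trend were chosen after seeing the data. No named window turned its sign and no overlap fell to its shifted values, but a plasmid median and a site mean, neither with a test of its own, changed sign. The pRSF median of rifampicin minus RNAP went from -0.48 to 0.14 with arrays scaled to a common spread. The mean flank difference at RpoD sites went from -0.06 to 0.11 when centred on the mode, to 0.04 after loess, to 0.03 in the series value table and with a flank of 1500 to 3000 bp, and to 0.02 without RNAP replicate 1. Under every alternative that changed them, overlaps between groups stayed above the highest of the shifted values (54 of 54, with 6 more that left out an array outside the pair) and the flank shares kept an interval below 0 (52 of 52). Of the counts, 148 of 202 for windows, 113 of 162 for sites (2 of them fixed by construction) and 26 of 34 for regions stayed within 1.5 times the value reported. Of the mean differences at sites, 48 of 74 moved by less than 1 SD of the RNAP arrays and 26 by more, and 7 could not move. For the named windows, sign and call were kept in 233 of 242 cases. Of all 242 cases, 72 left the value itself unchanged, and 162 of the 170 that changed it kept sign and call. The call was lost in 9, all for RpoD against RNAP: 5 after loess, 2 without RNAP replicate 1, 1 after normexp and 1 with the robust prior. The plasmid medians moved by more than 1 SD of the RNAP array medians in 20 of 44 cases. That SD was 0.0017 for pSLT, 0.045 for Col and 0.63 for pRSF, so this tally does not compare stability between plasmids. Unless a change in the number of windows, sites or probes tested or of arrays fitted is named below, the cause was not tested.

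Counts below are higher then lower, in the order of the report. With fewer windows, those of at least 3 probes gave RNAP 1529 and 1393, RpoD 1339 and 814, 620 higher after rifampicin and 511 lower for RpoD against rifampicin; windows of 1000 bp gave RNAP 1327 and 1276, RpoD 1216 and 691, RpoD against RNAP 233 and 230, rifampicin against RNAP 619 and 393, and RpoD against rifampicin 515 and 503. Loess gave RNAP 1181 lower, RpoD 549 lower, RpoD against RNAP 0 and 1 (764 and 633 at an unadjusted p under 0.05 in limma), 326 lower after rifampicin and 295 higher for RpoD against rifampicin. At RpoD sites it gave 10 lower summits and 166 and 10 for summit minus flank, at rifampicin sites 123 and 27, and 392 RNAP regions. Without dim probes, a filter that takes out low ChIP signal by its own construction and left 5319 of 8651 windows, RNAP had 163 and RpoD 195 lower windows, with 507 higher after rifampicin and 453 lower for RpoD against rifampicin.

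Mode centring gave 577 lower RpoD windows and 14 lower summits at RpoD sites. Normexp gave 277 higher windows for RpoD against RNAP, 66 lower summits and 85 lower summit minus flank values. A common spread gave 788 higher for RpoD against RNAP, 366 and 295 for rifampicin against RNAP, 373 lower for RpoD against rifampicin, 79 and 20 for summits and 79 and 21 for summit minus flank. Quantile normalisation gave 409 and 398 for rifampicin against RNAP, 269 and 384 for RpoD against rifampicin, 101 and 56 for summits and 141 higher for summit minus flank. Without saturated probes there were 22 lower summits and 197 higher values at rifampicin sites, and the second long-region median was -0.71, with an interval that includes 0. Without the chromosome trend there were 21 lower summits.

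Isolated sites alone, which are fewer, gave 93 and 9 for summits, 110 and 14 for summit minus flank, and 76 and 11 at rifampicin sites. A narrower summit window, which holds fewer probes, gave 123 higher summits, 120 and 31 for summit minus flank, and 141 and 33 at rifampicin sites. A height of 1.5 gave 366 RNAP regions. Runs of 5 probes gave 377 RNAP, 539 RpoD and 626 rifampicin regions, and a height at the 95th percentile gave 191, 260 and 239.

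Leaving out an array gave 1423 to 2322 and 892 to 2179 windows for RNAP, 426 to 1571 lower for RpoD, 64 to 670 and 83 to 493 for RpoD against RNAP, 427 to 939 lower for rifampicin against RNAP, and 366 to 1088 and 475 to 1032 for RpoD against rifampicin. It gave 28 to 88 lower summits at RpoD sites and 34 to 98 lower values at rifampicin sites. The lone array of a reduced group was assumed to vary like the other groups.

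The replicate numbers coincide with the slide and scan session for RNAP and RpoD, while the labels name no shared culture. The deviations of RNAP and RpoD with the same number correlated at 0.18 over windows, from 2 pairs. The replicate block gave 891 and 653 for RpoD against RNAP, as did the slide block, 1174 lower for rifampicin against RNAP and 1297 higher for RpoD against rifampicin, and moved no other count of windows or sites by more than 1.5 times. For RpoD against RNAP the replicate and slide blocks are the same fit, so they match by construction, though both enter the tallies. For rifampicin the replicate block groups its array with replicates 1 of RNAP and RpoD, which lay on another slide. Not run, for want of an annotation on the design sequence, were probes with several matches, other promoter windows and gaps, shorter gene bodies, and the gene list tests.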

Other observations

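The test against a wider range of ratios was chosen after the flank result had been seen, and the test against array noise was set before its result was seen. In untreated cells the median RNAP ratio over input on each plasmid lay below the chromosome median. This was not tested, and a ratio over input gives no amount of polymerase on a plasmid. On pSLT, the virulence plasmid of the species, the median RNAP level over 91 windows was -0.69 and -0.68 on replicates 1 and 2 (log2, relative to the chromosome median), the RpoD level -0.16 and -0.30, and the rifampicin level -0.45. On Col the median RNAP level over 87 windows was -1.11 and -1.04, the RpoD level -0.73 and -0.48, and the rifampicin level -0.06. On pRSF RNAP read -0.86 and -1.75, RpoD 0.80 and -0.94 and rifampicin -1.79, so that replicates of a group lay as far apart as the groups. The rifampicin minus RNAP medians of pSLT and Col were positive under each of the 8 alternatives run on the plasmids, at 0.20 to 0.54 and 0.57 to 1.05, and that of pRSF ranged from -0.59 to 0.14.

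Some RpoD sites had a low RNAP signal on the untreated arrays. Of 713 RpoD sites, 63 (8.84%) had an RNAP level under 0.5 on both untreated arrays, and 27 of these read at least 1 after rifampicin. At 24 RpoD sites polymerase read under 0.5 both untreated and after rifampicin. At the 63 sites the median rifampicin level was 0.91 (log2). Low values on the untreated arrays chose these sites, which by itself favours a higher level on another array. No gain with rifampicin can be read from them.

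Polymerase sites of the rifampicin array without RpoD signal numbered 226, with a median rifampicin level of 1.62, against 2.08 over all 979 sites. Noise unrelated to the other arrays, as the whole source, is argued against by untreated RNAP. Its median at these sites was 0.14, above the range of -0.15 to 0.09 (central 95%) at sites shifted along the chromosome. The excess was small, and of the 226 sites 48 read at least 1 on untreated replicate 1 and 15 on both untreated arrays. A candidate explanation is polymerase brought by another sigma factor, which was not tested because no other sigma factor was precipitated. Effects of single probes shared by all arrays were not tested either. The shifted sites do not carry such effects, so noise on top of them is not excluded.

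The lower share of polymerase next to RpoD sites after rifampicin may reflect polymerase that finished its transcripts while new polymerase was held at promoters. This was not tested. Against untreated replicate 2 the level at 750 to 1000 bp hardly differed, at 0.27 with rifampicin and 0.28 without. The lower share there came with a higher summit level, 1.90 against 1.27, and a higher level at 2000 to 3000 bp, 0.26 against 0.15. A wider range of ratios on the rifampicin array as the whole source is argued against by the flank share, a ratio within each array, which differed by -10.1 percentage points (-14.6 to -5.58) from the nearer of the untreated arrays. Across the alternatives run on it, that difference lay between -15.2 and -7.39, and each interval excluded 0. A difference between slides or cultures stays open, because the rifampicin array had its slide to itself and came from a single culture.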
